A study of Mus musculus with 11 samples.

How the data were processed

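RNA of the hippocampus was measured by sequencing in 11 libraries from male mice that had received saline or insulin through the nose. Per the labels' protocols, RNA was extracted with a column kit, libraries were made with a stranded total RNA kit and read from both ends, and mice were anaesthetized with isoflurane before the brain was removed. The labels state an insulin dose of 2.4 IU per nare. The titles call the 3 control libraries saline-treated, whereas their treatment label reads untreated and their time label reads 0 min; they are called saline here. The insulin groups hold 2 libraries at 15 min (replicates 1 and 3; replicate 2 was not analysed here), 3 at 1 h and 3 at 6 h. The labels give 3 animals per time and do not state outright that each library is 1 animal, so p-values measure the spread between these libraries. Each column of the series table was matched to its sample by the column name that the sample's description carries.

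The deposited values are log2 signals per gene symbol. The submitters' processing notes name bcl2fastq, Partek 6.7 and the mouse build GRCm38, without saying what each did; the aligner, the counter and the gene annotation are not given in the sources used here. From the values themselves, the authors' table is quantile-normalized between libraries: every library has the same minimum of -13.64, median of -3.20 and maximum of 16.00. The normalization was made over the genes with a value in each library, and that number differs, from 32037 to 33653 of 46202 rows. A gene with no value in a library is marked as such and was treated as missing. Because the same set of values was spread over differing numbers of genes, the median over the 26631 genes with a value in every library ran from -2.09 to -1.83 between libraries. Read counts cannot be recovered from these values, so the depth of each library is unknown and no counting interval can be given. No 2 libraries were identical; at most 0.0133% of cells agreed exactly between any 2 libraries.

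Tests were run in R 4.3.3 with limma 3.58.1 on the deposited log2 values. Rows in the lowest 40% by mean over the 11 libraries (missing values set at the lowest value of the table for this ranking only) were left out, which kept 27721 rows, 1950 of them with at least 1 missing value. A linear model with the 4 groups was fitted to all 11 libraries, so that the comparisons share 1 estimate of the spread. Moderated tests used empirical Bayes shrinkage with a mean-variance trend, were two-sided, and were adjusted by the Benjamini-Hochberg method at 0.05 over the rows tested in each comparison. All insulin libraries were also compared with saline in a 2-group fit, and a moderated F test covered the 3 contrasts against saline. A fold change is 2 raised to the difference of mean log2 signals. In text, ± is the SD between libraries unless it is called a standard error (SE). Changes are those of the deposited scale. On that scale the median log2 change over all rows tested was -0.14 at 15 min, -0.11 at 1 h and -0.04 at 6 h, and medians of gene lists are given relative to the median of all genes.

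Gene lists were 39 in number, fixed before the data were examined: 23 of pathways and responses and 16 of cell type or neighbouring region markers. They were tested with camera at a preset correlation of 0.01 between genes on the kept rows without missing values, adjusted over the 39 lists, and again with the correlation estimated for each list and with fry. Named genes followed a rule written before the data were examined. For each comparison with saline it took up to 8 rises and up to 8 falls, the largest past the threshold in which every insulin library lay beyond every saline library. Predicted and clone-named genes were passed over. Where fewer than 16 passed, the 4 smallest p-values in each direction were added, and these are described as not past the threshold. It also took the 3 members with the smallest p of each list past the list test, and a fixed panel, of which 13 genes are reported (Cpt1a, Cpt2, Acadvl, Hadha, Pdk4, Angptl4, Fasn, Slc2a1, Irs2, Insr, Fos, Arc and Egr1). Not every gene the rule took is reported. For other comparisons it took up to 4 in each direction, with predicted genes passed over there as well. Genes named to spell out a count of 5 or fewer, among them Gm36849, LOC105243316, Nr4a1 and Nr4a2, and the list members Eno1, Epm2a and Cers1 at 1 h, were chosen after their values were seen. Gene coordinates are those of the RefSeq annotation of GRCm38.p6, in which 37292 of the 46202 symbols were found.

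The tests were checked on simulated data with the real means, spreads and missing values. In the 15 min comparison, 46 of 100 genes with a log2 change of 1 and 74 of 100 with a change of 2 were recovered among 27721 rows, with 5 false calls. In the 1 h comparison the numbers were 48, 83 and 12, and in the 6 h comparison 53, 78 and 6. A list of 30 genes shifted by 0.5 was called in each of the 3 simulated comparisons, and none of the 38 other lists was. The simulated genes were drawn independently of each other, so this does not show how often correlated genes give false list calls. Alternatives planned before the data were examined were no filter, a filter on the lowest 60%, an offset of 1 on the linear scale, cyclic loess or another quantile normalization over the kept rows, a fit without trend, array weights, robust shrinkage, the replicate number as a block, only the 2 groups compared, and leaving out each library in turn. Alternatives added after seeing the data were the 18S ribosomal RNA level as a covariate, leaving out rows that move with it, leaving out rows with missing values, and missing values set at the lowest value.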

Results

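The study measured gene expression in the mouse hippocampus after insulin given through the nose, a route that delivers peptides to the brain, in the setting of lipid metabolism and the energy substrates of astrocytes. Log2 signals of 27721 gene rows were compared between saline (n = 3) and insulin at 15 min (n = 2), 1 h (n = 3) and 6 h (n = 3). The libraries held a value for 32941 to 33510 genes with saline, 32037 to 32427 at 15 min, 32133 to 32640 at 1 h and 32703 to 33653 at 6 h. Sequencing depth is unknown. All saline libraries carry the time label 0 min, so each insulin time was compared with controls of another sampling time. The numbers that end the column names also run by group. They are 1 to 3 for saline, 4 to 6 for 6 h, 7 and 9 for 15 min and 10 to 12 for 1 h. What they count is not stated, and any effect of that order cannot be told apart from that of insulin. The nuclear 18S ribosomal RNA row, Rn18s-rs5 (chromosome 17, 39846354 to 39848202), was lower at 1 h than with saline (limma adjusted p = 0.026), a call lost without saline replicate 3 (adjusted p = 0.087), without 1 h replicate 1, 2 or 3 (0.11, 0.093 and 0.065) and with only the 2 groups compared (0.064). Its log2 signal was 14.28 ± 1.54 with saline (n = 3), 10.08 ± 0.58 at 15 min (n = 2), 10.30 ± 0.18 at 1 h (n = 3) and 11.63 ± 0.58 at 6 h (n = 3). In saline replicate 1 it stood at 16, the maximum that every library shares, so the size of its changes cannot be read exactly.

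The first comparison asked which transcripts differed 15 min after insulin. Klf2, a transcription factor of vessel and immune cells, was 4.59-fold higher (log2 change 2.20, SE 0.21), Klf4 3.75-fold (1.91, SE 0.15), Fosb 3.48-fold (1.80, SE 0.26) and Fos 3.11-fold (1.64, SE 0.14), with adjusted p of 0.0084, 0.0034, 0.030 and 0.0034 by limma. Fos, a marker of recent neuronal activity (chromosome 12, 85473890 to 85477274), went from a log2 signal of 0.96 ± 0.05 (n = 3) to 2.60 ± 0.06 (n = 2). Pdk4, the kinase that restrains pyruvate dehydrogenase and so glucose oxidation (chromosome 6, 5483351 to 5496278), rose 2.41-fold (adjusted p = 0.020). Cyr61, a secreted matrix protein, rose 2.30-fold (adjusted p = 0.014). In all, 12 genes rose and 54 fell.

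Immediate early genes moved together at 15 min. Of 30 measured members, 5 rose over all genes (Fos, Fosb, Klf4, Cyr61 and Nr4a1) and 17 rose when adjusted over the list alone; the median lay 0.81 above that of all genes in log2 (camera adjusted p = 3.0e-24). With an estimated correlation the adjusted p was 0.026. Egr1 and Arc, of the same class, had log2 changes of 1.31 (adjusted p = 0.14) and 0.63 (adjusted p = 0.34). Among 20 glucocorticoid and stress responsive genes, 3 rose (Sgk1 2.19-fold, Fkbp5 2.15-fold and Pdk4), and 13 rose and 1 fell when adjusted over the list alone. The median of that list lay 0.80 above all genes (camera adjusted p = 1.0e-19). With an estimated correlation the adjusted p was 0.036. The call of Sgk1, a kinase induced by steroids, was near the threshold (adjusted p = 0.047) and was lost in 10 of 11 runs that left out 1 library and after cyclic loess (adjusted p = 0.051). The call of Nr4a1 (adjusted p = 0.047) was likewise lost in 10 of 11 such runs. FOXO target genes, transcripts driven by factors that insulin signalling excludes from the nucleus, lay higher as a list, with 1 of 22 members past the threshold over all genes (Pdk4) and 4 adjusted over the list alone (adjusted p = 0.00012; adjusted p = 0.040 with an estimated correlation). The named members Bcl6 and Klf15 had log2 changes of 0.67 (adjusted p = 0.072) and 0.55 (adjusted p = 0.075). After cyclic loess with an estimated correlation the adjusted p was 0.055 for immediate early genes and 0.065 for each of the other lists named here.

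Lists of lipid handling did not pass at 15 min with all libraries, and no member of them rose or fell over all genes. Camera adjusted p was 0.066 for the 27 genes of fatty acid oxidation and the carnitine shuttle, 0.65 for 17 of fatty acid uptake, 0.95 for 22 of fatty acid synthesis, 0.30 for 25 of cholesterol synthesis and 0.83 for 21 of triglycerides and lipid droplets. For 28 sphingolipid genes it was 0.95 and for 8 ketone body genes 0.12. The list of fatty acid oxidation passed, lying lower, without 15 min replicate 1 (adjusted p = 0.00079) and without 6 h replicate 2 (adjusted p = 0.039). Adjusted over the list alone, 2 members fell in fatty acid synthesis and 1 in the triglyceride list. The carnitine acyltransferases Cpt1a and Cpt2 had log2 changes of -0.08 (SE 0.15) and -0.23 (SE 0.14), the oxidation enzymes Acadvl and Hadha of -0.19 (SE 0.10) and -0.21 (SE 0.09), the lipase inhibitor Angptl4 of -0.61 (SE 0.34) and fatty acid synthase, Fasn, of 0.18 (SE 0.20). Their adjusted p ran from 0.34 to 0.83. The insulin receptor gene Insr had a log2 change of -0.02 (SE 0.15), its substrate Irs2 of 0.34 (SE 0.20) and the glucose transporter Slc2a1 of 0.63 (SE 0.16; adjusted p = 0.14). Glycolysis (22 genes), glycogen (15), pyruvate dehydrogenase and the tricarboxylic acid cycle (29, of which Pdk4 rose), PPAR targets (22, of which Pdk4 rose) and inflammatory genes (18) had adjusted p of 0.54, 0.25, 0.75, 0.75 and 0.096. The inflammatory list passed, lying higher, without 15 min replicate 3 (0.011) and without 6 h replicate 2 (0.040).

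Other lists passed at the preset correlation. Hypoxia responsive genes (18; Ddit4, Slc2a1 and P4ha1 with the smallest p) and 13 mitochondrially encoded genes (COX1, COX2 and ND4L) lay higher, with adjusted p of 0.00089 and 0.00066, and adjusted p = 0.040 each with an estimated correlation. The mitochondrially encoded list had an adjusted p of 0.11 after cyclic loess. Excitatory synapse genes (36; Snap25, Homer1 and Shank3; adjusted p = 5.1e-06), heat shock genes (25; Dnajb1, Hspa1b and Hsph1; 0.00012), insulin and PI3K pathway genes (34; Pdpk1 and Ptpn1; 0.013) and clock genes (18; Nfil3, Per2 and Ciart; 0.018) lay higher. Nuclear encoded oxidative phosphorylation genes (71; Cox6b1, Ndufv3 and Atp5j2; 0.00053) and ribosomal proteins (62; Rps16, Rps14 and Rps18; 0.018) lay lower. With an estimated correlation these 6 lists had adjusted p of 0.60, 0.60, 0.60, 0.26, 0.67 and 0.72. Leaving out 15 min replicate 3 turned the direction of the 2 lower lists (adjusted p = 0.82 and 0.44) and ended the calls of the synapse, insulin pathway and clock lists (0.44, 0.33 and 0.14). Without saline replicate 2 the insulin pathway and ribosomal lists were not called (0.084 and 0.12).

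Marker lists of other cells and regions passed at 15 min as well. Striatum (9; Drd1 and Penk), interneuron (10; Gad1, Gad2 and Slc32a1), neocortex (9; Nr4a2 and Tbr1) and choroid plexus (13; Kl, Clic6 and Prlr) markers lay higher, with adjusted p of 0.00066, 0.011, 0.011 and 0.013, and pericyte markers (9; Pdgfrb, Vtn and Tagln) lay lower (0.018). With an estimated correlation the adjusted p was 0.60, 0.60, 0.23, 0.67 and 0.60. Of the 2 libraries, replicate 1 carried the choroid plexus list, which had an adjusted p of 0.98 without it and of 0.051 without saline replicate 3; Kl was at 0.59 in replicate 1 and -1.19 in replicate 3, against a saline mean of -0.94. Without 15 min replicate 3 the interneuron, neocortex and pericyte lists were not called (0.53, 0.27 and 0.19), nor was the pericyte list without saline replicate 1 (0.078). Endothelial, microglial, meningeal and thalamic markers had adjusted p of 0.096, 0.10, 0.54 and 0.11, and those of astrocytes, neurons, dentate granule neurons, pyramidal neurons, oligodendrocytes, their precursors and blood 0.75, 0.65, 0.15, 0.28, 0.65, 0.87 and 0.47. Of these, some passed without 1 library: endothelial (0.034), microglial (0.046), thalamic (0.043) and pyramidal (0.038) without 15 min replicate 1, blood without 15 min replicate 3 (0.00054), microglial without saline replicate 1 (0.012), and endothelial and thalamic without saline replicate 3 (0.027 and 0.013).

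The named falls at 15 min were larger than the rises. Cd44 was 18.7-fold lower, Tbx20 15.5-fold, Lars2 15.2-fold, Il31ra 15.0-fold, Dnah7b 12.4-fold, Gnb1l 11.8-fold and Rsph3b 10.4-fold, with adjusted p from 0.014 to 0.047. The fold of Tbx20 rests on low signal at 15 min (-8.307 and -8.72), near the filter's cutoff of -8.66. Dnah7b, a dynein heavy chain of motile cilia (chromosome 1, 46066071 to 46373551), went from 2.03 ± 0.68 (n = 3) to -1.60 ± 0.01 (n = 2). Of the 54 genes that fell, 23 had deviations from their group means that correlated above 0.5 with those of Rn18s-rs5, against 4.80% of the 25771 rows kept without a missing value. The calls of Fos and Klf4 held in all 11 runs that left out 1 library, while those of Fosb, Fkbp5 and Tbx20 were lost in 9, that of Lars2 in 8, Dnah7b in 5, Pdk4, Cyr61, Cd44 and Il31ra in 4 each, Gnb1l in 3, Rsph3b in 2 and Klf2 in 1. Without rows that move with Rn18s-rs5 the calls of Pdk4, Fosb, Fkbp5, Sgk1 and Nr4a1 were lost (adjusted p = 0.052, 0.065, 0.071, 0.075 and 0.075). Leaving out other rows does not alter the log2 changes of these genes, only their tests. After cyclic loess 10 genes rose and 21 fell, all 31 among the genes called on the deposited values, so that the share of rises went from 18.2% to 32.3%. With only the 2 groups compared 1 gene was called, Fos. Leaving out each of the 11 libraries moved the count by more than 1.5 times: to 18, 21 and 19 without saline replicates 1, 2 and 3, to 6 and 5 without 15 min replicates 1 and 3, to 33, 36 and 40 without the 1 h replicates and to 40, 103 and 41 without the 6 h replicates.

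**Figure D1:**
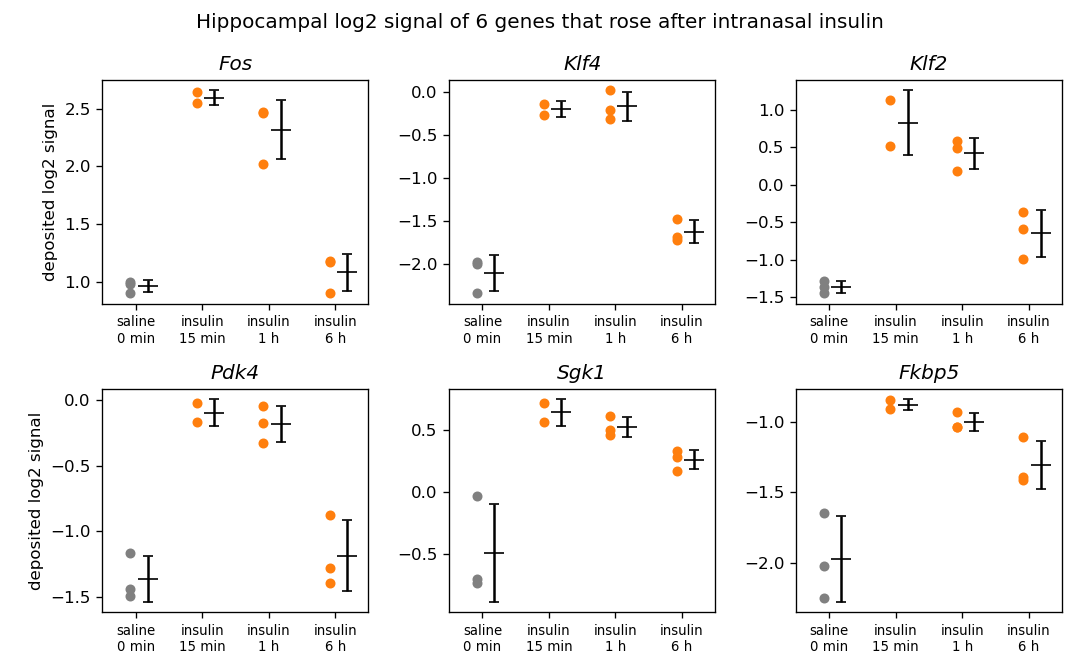
Deposited log2 signal (vertical axis) of Fos, Klf4, Klf2, Pdk4, Sgk1 and Fkbp5 in each library, by group on the horizontal axis, saline in grey and insulin in orange. Dashes with bars are the group mean ± SD; for Fos the means are 0.96 with saline, 2.60 at 15 min, 2.32 at 1 h and 1.08 at 6 h.

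The second comparison asked which transcripts differed 1 h after insulin. Klf4 was 3.84-fold higher than with saline, Klf2 3.45-fold, Fosb 3.39-fold, Zbtb16 3.29-fold, Fos 2.56-fold, St8sia3 2.45-fold, Arl4d 2.38-fold and Pdk4 2.27-fold. Their adjusted p by limma ran from 0.0013 for Klf4 to 0.045 for Arl4d. Zbtb16 is a transcription factor induced by glucocorticoids, St8sia3 a sialyltransferase and Arl4d a small GTPase. The calls of Zbtb16 and Arl4d were lost in 9 of 11 runs that left out 1 library each, and that of St8sia3 in 4. Il31ra was 24.3-fold lower, Cd44 22.5-fold, Lars2 22.1-fold, Dnah7b 15.8-fold, Rn18s-rs5 15.7-fold, Tbx20 15.6-fold and Gphn 14.6-fold, with adjusted p from 0.0021 to 0.026. The call of Tbx20 was lost without saline replicate 3 and without 1 h replicates 1 and 2 (adjusted p up to 0.069), with the offset (adjusted p = 0.18) and with only the 2 groups compared. Its 1 h signal was low (-8.225, -8.762 and -8.587), near the filter's cutoff of -8.66. Lars2 encodes the mitochondrial leucyl-tRNA synthetase and Gphn the inhibitory synapse scaffold gephyrin. Within groups, the deviations of the named falls at 15 min and 1 h correlated with those of Rn18s-rs5 at 0.577 for Cd44, 0.601 for Lars2, 0.632 for Dnah7b, 0.695 for Il31ra, 0.708 for Gphn, 0.751 for Tbx20, 0.839 for Rsph3b and 0.923 for Gnb1l. Rn18s-rs5 varied most with saline (SD 1.54, against 0.18 to 0.58 in the insulin groups), where replicate 1 stood at the shared maximum of 16. These correlations thus rest largely on the saline libraries. Whether these genes hold sequence like that of 18S was not analysed here.

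Of the 30 immediate early genes, 5 rose at 1 h over all genes (Fos, Fosb, Klf4, Nr4a1 and Nr4a2) and 11 adjusted over the list alone, with a median 0.55 above all genes (adjusted p = 2.7e-15, and adjusted p = 0.039 with an estimated correlation). The calls of Fosb, Nr4a1 and Nr4a2 were lost in 3, 6 and 5 of 11 runs without 1 library. Egr1 had a log2 change of 1.14 (adjusted p = 0.10) and Arc one of 0.11 (adjusted p = 0.88). Of 20 glucocorticoid and stress responsive genes, 5 rose (Zbtb16, Pdk4, Sgk1, Fkbp5 and Nfkbia), and 13 rose and 1 fell adjusted over the list alone. Fkbp5, a chaperone of the steroid receptors, was 1.97-fold higher and the NF-kappaB inhibitor Nfkbia 1.73-fold. The calls of Sgk1, Fkbp5 and Nfkbia were lost in 5, 4 and 4 of 11 runs without 1 library, and with only the 2 groups compared (adjusted p = 0.0667, 0.0583 and 0.0501). The list had an adjusted p of 1.2e-17, and 0.039 with an estimated correlation. Of 22 FOXO targets, 2 rose (Pdk4 and Klf15, 1.59-fold), and 6 rose and 1 fell adjusted over the list alone (adjusted p = 5.2e-05, and adjusted p = 0.039 with an estimated correlation). The call of Klf15 was lost in 4 of those 11 runs. Trib1, the third named member, had a log2 change of 0.75 (adjusted p = 0.061). After cyclic loess with an estimated correlation, each of these 3 lists had an adjusted p of 0.079.

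Heat shock and unfolded protein response genes lay higher at 1 h (adjusted p = 1.1e-11, and adjusted p = 0.40 with an estimated correlation), with 0 of 25 members past the threshold over all genes and 10 rises adjusted over the list alone. The co-chaperone Dnajb1 had a log2 change of 0.98 (SE 0.20), Creld2 of 0.60 (SE 0.13) and Sdf2l1 of 0.57 (SE 0.14). Hypoxia responsive genes (Ddit4, Slc2a1 and P4ha1; adjusted p = 0.026), striatum markers (Drd1, Tac1 and Rgs9; 0.023) and blood markers (S100a8, Slc4a1 and S100a9; 0.048) lay higher. Nuclear encoded oxidative phosphorylation genes (Cox6b1, Ndufv2 and Atp5c1; 0.034) and pericyte markers (Pdgfrb, Vtn and Kcnj8; 0.029) lay lower. With an estimated correlation these 5 lists had adjusted p of 0.17, 0.81, 0.81, 0.81 and 0.81. Replicate 2 carried the blood list, with S100a8 at 0.33 against -2.17 and -3.26 in the other 1 h libraries and a saline mean of -3.17. The adjusted p of that list was 0.63 without 1 h replicate 2, 0.16 without saline replicate 3, and 0.056, 0.083 and 0.053 without 6 h replicates 1, 2 and 3. The hypoxia list was not called without 1 h replicate 2 (0.075), the striatum list without 1 h replicate 3 (0.92) or saline replicates 1 and 2 (0.058 and 0.061), the oxidative phosphorylation list without saline replicate 2 (0.48) or 1 h replicates 1, 2 and 3 (0.061, 0.057 and 0.087), and the pericyte list without saline replicate 1 (0.13) or 1 h replicate 3 (0.12).

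No lipid list passed at 1 h. Camera adjusted p was 0.29 for fatty acid oxidation, 0.995 for uptake, 0.96 for fatty acid synthesis, 0.35 for cholesterol, 0.41 for triglycerides, 0.21 for ketone bodies and 0.59 for sphingolipids. In the last list the ceramide synthase gene Cers1 rose by 1.13 in log2 (SE 0.20, adjusted p = 0.035), a call lost in 7 of 11 runs without 1 library. The panel genes Cpt1a, Cpt2, Acadvl, Hadha, Angptl4 and Fasn had log2 changes of -0.05, -0.07, -0.15, -0.20, -0.31 and 0.23, with adjusted p from 0.29 to 0.89. Insr, Irs2 and Slc2a1 had log2 changes of -0.08, 0.33 and 0.65 (adjusted p = 0.82, 0.42 and 0.069). Eno1 of the glycolysis list fell by 0.29 on the log2 scale (adjusted p = 0.037) and Epm2a of the glycogen list fell by 0.55 (adjusted p = 0.049), each lost in 10 of those 11 runs. Those 2 lists had adjusted p of 0.82 and 0.43. The remaining lists had adjusted p from 0.085 to 0.995. Of these, endothelial, neocortex and thalamic markers passed without saline replicate 3 (0.046 each), microglial markers without saline replicate 1 (0.028) and interneuron markers without 1 h replicate 2 (0.027).

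At 1 h 36 genes rose and 207 fell, and 35 of those that fell moved with Rn18s-rs5 in the sense given above. Cyclic loess gave 40 rises and 96 falls, of which 31 and 96 were also called on the deposited values, and raised the share of rises from 14.8% to 29.4%. With only the 2 groups compared 138 genes were called. The count went to 59, 86 and 65 without saline replicates 1, 2 and 3, to 42 and 63 without 1 h replicates 1 and 2, and to 477 and 155 without 6 h replicates 2 and 3.

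**Figure D2:**
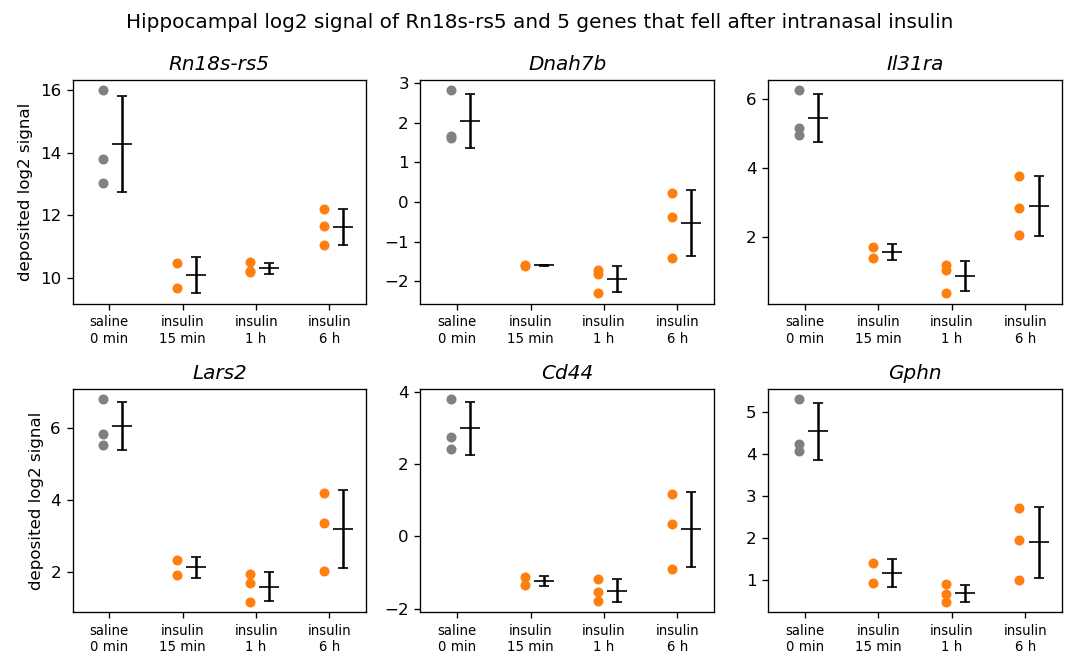
Deposited log2 signal (vertical axis) of Rn18s-rs5, Dnah7b, Il31ra, Lars2, Cd44 and Gphn in each library, by group on the horizontal axis, saline in grey and insulin in orange. Dashes with bars are the group mean ± SD; the Rn18s-rs5 means are 14.28 with saline, 10.08 at 15 min, 10.30 at 1 h and 11.63 at 6 h.

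The third comparison asked what differed 6 h after insulin. No gene passed the threshold by limma, and 6 did when missing values were set at the lowest value. The smallest adjusted p was 0.17. Of 27707 rows tested, 1934 had an unadjusted p under 0.05, 762 higher and 1172 lower, where a share of 0.05 is expected without any change. The smallest p-values upward belonged to Cers1 (log2 change 1.15, SE 0.20), Csf2ra (1.62, SE 0.32), Ccdc86 (0.50, SE 0.10) and Cyp2g1 (3.46, SE 0.71), and downward to Jarid2 (-1.98, SE 0.27), Arhgap21 (-1.87, SE 0.26), Camk1d (-1.92, SE 0.27) and Kcnip1 (-1.94, SE 0.27), none past the threshold. The signal of Cyp2g1 with saline was low (-10.13, -7.629 and -7.376). Within groups, the deviations of Jarid2, Arhgap21, Camk1d and Kcnip1 correlated with those of Rn18s-rs5 at 0.873, 0.888, 0.896 and 0.887. These correlations too rest largely on the saline libraries. Fos had a log2 change of 0.12 (SE 0.12), Pdk4 of 0.18 (SE 0.15), Egr1 of 0.44 (SE 0.29) and Arc of -0.24 (SE 0.26). The lipid genes Cpt1a, Cpt2, Acadvl, Hadha, Angptl4 and Fasn had log2 changes of -0.10, -0.14, -0.09, -0.13, 0.08 and 0.27, and Insr, Irs2 and Slc2a1 of -0.01, 0.20 and 0.26.

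Glucocorticoid and stress responsive genes lay higher at 6 h as a list, with 19 of 20 members above 0, none past the threshold over all genes and 10 rises adjusted over the list alone (adjusted p = 1.4e-13, and adjusted p = 0.093 with an estimated correlation). Sgk1, Ddit4 and Hif3a had log2 changes of 0.75, 0.61 and 0.99. Choroid plexus and ependyma markers lay lower, with a median 1.57 below that of all genes and all 13 members below 0 (adjusted p = 3.6e-06, and adjusted p = 0.71 with an estimated correlation). Folr1 went from -1.33 ± 0.15 to -4.09 ± 1.81 (n = 3 each). Foxj1 and Tmem212 had log2 changes of -0.38 and -0.66. Mitochondrially encoded genes (ND4L, COX2 and ND2; adjusted p = 0.00073) and immediate early genes (Klf4, Fosb and Trib1; 0.017) lay higher. Oxidative phosphorylation genes (Ndufa12, Cox6b1 and Atp5c1; 0.011), endothelial markers (Slco1a4, Tek and Kdr; 0.019), pericyte markers (Vtn, Abcc9 and Cald1; 0.030) and blood markers (S100a8, Hba-a2 and Hbb-bt; 0.042) lay lower. With an estimated correlation the adjusted p was 0.093 for the mitochondrially encoded list and 0.71 for each of these others. Calls were lost without saline replicate 1 for immediate early genes and endothelial, pericyte and blood markers (adjusted p = 0.087, 0.35, 0.24 and 0.14) and without saline replicate 2 for immediate early genes, oxidative phosphorylation and blood markers (0.055, 0.37 and 0.22). They were lost without 6 h replicate 1 for blood markers (0.058), without 6 h replicate 2 for immediate early genes and pericyte and blood markers (0.18, 0.18 and 0.093), and without 6 h replicate 3 for immediate early genes, oxidative phosphorylation and endothelial, pericyte and blood markers (0.059, 0.10, 0.24, 0.16 and 0.16). Other lists passed only without 1 library: heat shock genes, lying higher, without 6 h replicate 2 (0.0059), interneuron and striatum markers, lying higher, without saline replicate 3 (0.020 and 0.032) or 6 h replicate 1 (0.048 and 0.036), the latter also without 1 h replicate 3 (0.023), and without 6 h replicate 1 precursors of oligodendrocytes, lying higher (0.043), and pyruvate dehydrogenase and the tricarboxylic acid cycle, lying lower (0.045). The lipid lists had adjusted p of 0.30 for oxidation, 0.76 for uptake, 0.91 for synthesis, 0.68 for cholesterol and 0.30 for triglycerides.

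The times after insulin were then compared with one another. Fos was 2.36-fold lower at 6 h than at 1 h and 2.86-fold lower than at 15 min, with adjusted p of 0.015 and 0.019. Klf4 was 2.75-fold and 2.69-fold lower, with adjusted p of 0.015 and 0.034. The predicted gene Gm36849 was higher at 6 h than at 1 h, by 2.13 in log2 (SE 0.21; adjusted p = 0.015). These were the 3 and 2 genes called between 6 h and the earlier times, and the fits of only the 2 groups called none. Between 6 h and 1 h the calls of Fos, Klf4 and Gm36849 were lost in 7, 5 and 7 of 11 runs without 1 library, and between 6 h and 15 min those of Fos and Klf4 in 7 and 9. Between 1 h and 15 min no gene passed by limma. Of 27645 rows tested, 966 had an unadjusted p under 0.05, a smaller share than the 0.05 expected without any change. Pdk4 was lower at 6 h than at 1 h by a log2 change of -1.01, which did not pass (adjusted p = 0.13). As lists, immediate early genes lay lower at 6 h than at 1 h (adjusted p = 9.0e-12; adjusted p = 0.096 with an estimated correlation) and than at 15 min (adjusted p = 4.4e-17; adjusted p = 0.071 with an estimated correlation).

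Other lists passed between the times at the preset correlation, and none of them passed with an estimated correlation. At 6 h against 1 h, heat shock genes (adjusted p = 4.5e-09, and 0.61 with an estimated correlation), choroid plexus markers (2.1e-06 and 0.67), blood markers (4.9e-06 and 0.58), FOXO targets (5.9e-05 and 0.096), glucocorticoid and stress responsive genes (0.0011 and 0.61) and meningeal markers (0.041 and 0.9997) lay lower. The stress responsive list was not called without 6 h replicate 3 (0.12), nor the meningeal list without 1 h replicates 2 and 3 and 6 h replicate 2 (0.39, 0.065 and 0.43). At 6 h against 15 min, choroid plexus markers (1.2e-10 and 0.42), excitatory synapse genes (4.6e-05 and 0.70), FOXO targets (0.0014 and 0.16), stress responsive genes (0.0014 and 0.61), blood markers (0.0093 and 0.70), heat shock genes (0.014 and 0.88), dentate granule neuron markers (0.014 and 0.42) and hypoxia responsive genes (0.019 and 0.23) lay lower. Without 15 min replicate 1 the blood and dentate lists were not called (0.92 and 0.081), without 15 min replicate 3 the synapse and heat shock lists (0.51 and 0.35), without 6 h replicate 2 the heat shock list (0.18), and without 6 h replicate 3 the heat shock, dentate and hypoxia lists (0.17, 0.16 and 0.098).

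At 1 h against 15 min, excitatory synapse genes (adjusted p = 1.3e-06, and 0.89 with an estimated correlation), immediate early genes (0.00068 and 0.78), dentate granule neuron markers (0.00068 and 0.51) and choroid plexus markers (0.0010 and 0.89) lay lower. Ribosomal proteins (0.00097 and 0.89), heat shock genes (0.00097 and 0.89) and cholesterol genes (0.0013 and 0.78) lay higher, the last with 24 of 25 members above 0 and none past the threshold by itself. Only the dentate list among these 7 kept its call in all 11 runs without 1 library. Without 15 min replicate 1 the choroid plexus and heat shock lists were not called (0.96 and 0.38), without 15 min replicate 3 the synapse and immediate early lists (0.89 and 0.32), and the ribosomal list turned direction (0.23). Without 1 h replicate 1 the choroid plexus, ribosomal and cholesterol lists were not called (0.23, 0.052 and 0.066), and without 1 h replicate 2 the heat shock list (0.33).

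Over the 3 insulin times, 101 genes differed by the moderated F test. All 8 insulin libraries against saline gave 4 rises and 29 falls. Cers1 rose by 1.05 in log2 (SE 0.17), Sgk1 by 0.95 (SE 0.15) and Ddit4, a stress-induced inhibitor of mTOR signalling, by 0.65 (SE 0.10), and the predicted gene LOC105243316 by 0.74. Cd44, Lars2, Il31ra and Dnah7b fell by 3.79, 3.73, 3.67 and 3.36. Each of these 8 calls was lost in 6 to 10 of 11 runs without 1 library. The fit without trend called 0 genes. The count of 33 went to 0, 1 and 3 without saline replicates 1, 2 and 3, to 10 without either 15 min library, to 9 and 15 without 1 h replicates 2 and 3, and to 63 without 6 h replicate 1.

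Comparisons against the same saline libraries share their chance values. Of 12 genes that rose at 15 min and 36 at 1 h, 10 were shared, against 0.0156 for independent lists, and of 54 and 207 that fell, 46 were shared, against 0.404. Across genes, which are not independent replicates, the log2 changes at 15 min and 1 h correlated at 0.614 against 0.446 in 100 simulations without effects, with a covariance of 0.140 against 0.0571. For 15 min and 6 h the correlation was 0.407 against 0.448 and the covariance 0.0829 against 0.0573; for 1 h and 6 h the correlation was 0.528 against 0.501 and the covariance 0.0999 against 0.0573. The 3 saline libraries cannot be split so that each part keeps 2, so part of the excess may come from the shared controls.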

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

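The tests of 18S, normalization, background and handling below were chosen after the results were seen; the counts of other splits were planned. The boundary of 4-fold, the correlation of 0.5 and the use of Rn18s-rs5 as a covariate were also chosen after values had been seen. For the rises the covariate took the place of the correlation within groups, which had a median of -0.121 (-0.428 to 0.0722 without any 1 library) and left the question undecided. 5 results were picked out because the signal differed between insulin times by a direct test. No saline library was taken at those times, so a difference in the effect of insulin itself is not shown. Fos changed by -1.24 (log2) from 1 h to 6 h and by -1.52 from 15 min to 6 h, Klf4 by -1.46 and -1.43, and Gm36849 by 2.13 from 1 h to 6 h. No group has 4 or more libraries, so single libraries were not tested for standing apart.

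The first pattern is the fall of many transcripts by 4-fold or more at 15 min or 1 h, in libraries that also held less Rn18s-rs5. One candidate explanation is the 18S ribosomal RNA content of the libraries, with reads of ribosomal origin landing on these genes. Within groups, the 45 such genes had a median correlation with Rn18s-rs5 of 0.462 (0.254 to 0.651 without any 1 library) with a permutation p of 0.148 over 432 shuffles. The 167 smaller falls had one of 0.150 (-0.173 to 0.3035 without any 1 library, permutation p = 0.345). With Rn18s-rs5 as a covariate the median change at 1 h went from -2.90 (median SE 0.38) to -2.17 (0.74) for the 45 genes. Of these, 35 lay more than 2 standard errors from 0, counted in either direction. For the 167 it went from -0.85 (0.13) to -0.75 (0.31), and 115 lay that far from 0. No gene was called between any of the groups with the covariate, because the errors grew. Both shares are short of the 80% set for the rises below, and both correlations lie between the bounds set for them (0.1 and 0.5), so the 18S content and an effect of insulin cannot be told apart for either set.

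The second pattern is the excess of falls over rises at 1 h. The authors' quantile normalization over differing numbers of genes is one candidate: after cyclic loess 70.6% of the 136 called genes were lower, against 207 of 243 on the deposited values, but without single libraries that share ran from 50.3% to 85.7%. Background from genomic DNA or unspliced RNA is another: 118 olfactory, vomeronasal and trace amine receptor genes, which the hippocampus hardly expresses, lay -0.22 from rows of matched mean, lower than all 10000 random matched sets but short of the 0.3 set for the test, and they lie near the floor. Both remain open and cannot be told apart from an effect of insulin, and no other biological explanation was tested.

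The third pattern is the joint rise of immediate early and glucocorticoid responsive genes at 15 min and 1 h. All 11 called members, 100%, were also called after cyclic loess at 15 min or 1 h (Sgk1 at 15 min was not). This argues against the differences between libraries that cyclic loess removes as the whole cause. Cyclic loess was run on the quantile-normalized values, so it does not undo the authors' normalization. The members were also picked as called on those values, so that normalization is not excluded. The 18S content stays open. With Rn18s-rs5 as a covariate 90.9% of the members (10 of 11) stayed more than 2 standard errors above 0 at 1 h. Their median change went from 1.08 (median SE 0.15) to 1.02 (0.35), though none was then called because the errors grew. This cannot decide the question, since Rn18s-rs5 was at least 13.05 with saline and at most 10.51 at 15 min and 1 h. The adjustment thus rests on differences within groups, where saline replicate 1 stood at the shared maximum. The members were also picked as called in the same libraries. Handling, anaesthesia or time of sampling stays open, since 0 saline libraries were taken at the insulin times, so it cannot be told apart from an effect of insulin. The order of the column numbers, which run by group, stays open likewise.

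Other splits of the same libraries were counted. For 1 h against saline the real split called 243 genes and the highest of the other 9 called 0, so 1 of 10 splits called as many, and 10 splits are too few for a share under 0.05. For 6 h against saline all 10 splits called 0, and for 6 h against 1 h the real split called 3 and the highest other 1, in 10 splits each. Of list tests, the real split called 9 at 1 h and the highest other 12 (6 splits of 10 called as many). At 6 h these were 8 and 16 (2 of 10), and 10 splits are again too few for a share under 0.05. Another split called as many lists at both times, the outcome set beforehand for chance. The number of lists called at the preset correlation thus sets neither time apart from other splits. For all insulin against saline, 2 of 100 splits drawn from 165, the real one included, called at least 33 genes. That share is under the 0.05 planned as going against chance, and splits not drawn were not counted. The other of these 2 splits called far more genes than the real one, so the share does not set the treatment apart from other groupings. The highest other called 915 and set 15 min replicate 3, 1 h replicate 3 and 6 h replicate 2 apart, which points to a structure of the samples beyond the treatment. These 3 libraries were also the highest of the 11 for 4 named markers of interneurons, striatum and neocortex (Slc32a1, Gad2, Rgs9 and Tbr1; Gad2 at 1.14 to 1.44, and at most 1.09 in the others), though not for Gad1, Drd1, Penk, Tac1 or Nr4a2. The library 6 h replicate 2 had the lowest mean rank correlation with the other libraries, 0.983.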

How the results depend on the processing

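The covariate, the rows moving with 18S and both treatments of missing values were chosen after seeing the data; the other alternatives were planned. Fos at 15 min and 1 h and Klf4, Klf2, Pdk4, Cd44, Il31ra, Gphn, Lars2 and Dnah7b at 1 h kept their calls in all 11 runs without 1 library and in every other alternative that tested them, the 18S covariate excepted. Leaving out rows that move with 18S removed Klf4, Cd44, Il31ra, Gphn, Lars2 and Dnah7b themselves, so it did not test them. Their correlations with Rn18s-rs5 within groups ran from 0.567 for Klf4 to 0.708 for Gphn. Robust shrinkage and leaving out rows with missing values moved no count of genes by over 1.5 times. The depth is unknown, so its limits cannot be given. The cause was not tested for any change below, except where fewer libraries or genes entered.

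Genes called at 15 min and 1 h were 112 and 394 with the offset, 31 and 136 after cyclic loess, 33 and 140 after quantile normalization again, 140 and 1751 with array weights, 1 and 138 with only the 2 groups compared, and 0 and 0 with the 18S covariate. At 15 min they were 114 without trend and 5 without rows moving with 18S. With missing values at the lowest value, 6 genes were called at 6 h, 10 between 1 h and 15 min, 9 between 6 h and 1 h, 24 between 6 h and 15 min and 21 for all insulin. Between 6 h and 1 h the offset gave 1, array weights 16, and only the 2 groups compared and the covariate 0. Between 6 h and 15 min the fit without trend gave 6, leaving out rows moving with 18S 1, and only the 2 groups compared and the covariate 0. For all insulin no filter gave 11, the stricter filter 56, the offset 80, no trend 0, array weights 1087, leaving out rows moving with 18S 0 and the mean of the 3 time contrasts 125. The F test gave 49 after loess, 47 after quantile normalization again, 725 with array weights and 20 without rows moving with 18S; it could not be run with only the 2 groups compared, and the covariate was not run for it or for all insulin. List tests called 5, 3 and 0 lists at 15 min, 1 h and 6 h with an estimated correlation and 5, 4 and 1 with fry. With an estimated correlation all of them lay higher. With fry 3 lay higher and 2 lower at 15 min, 3 higher and 1 lower at 1 h, and 1 higher at 6 h. The 2 methods thus did not call the same lists.

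With the replicate number as a block, 38 genes were called at 15 min, 159 at 1 h, 0 between 6 h and 1 h, 0 between 6 h and 15 min, 0 for all insulin and 40 by the F test. The numbers were not taken to pair the libraries, since only 7 of 15 pairs with the same number had deviations correlating over 0.1 (-0.056 to 0.237, mean 0.0893, against a mean of -0.0446 for other pairs). As a hint from the data, 6 of 11 libraries correlated best with their own number.

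Without any 1 library, the range was 5 to 103 genes at 15 min, 42 to 477 at 1 h, 0 to 0 at 6 h, 0 to 0 between 1 h and 15 min, 0 to 4 between 6 h and 1 h, 0 to 3 between 6 h and 15 min, 0 to 63 for all insulin and 17 to 124 by the F test. Lists called ranged from 10 to 20, 6 to 11 and 3 to 11 at the 3 times. A group left with 1 library was assumed to vary like the others. Correlations without 1 saline library were 0.647 to 0.666 for 15 min and 1 h, 0.465 to 0.495 for 15 min and 6 h and 0.583 to 0.610 for 1 h and 6 h. Without 15 min replicate 3 the list cytosolic ribosomal proteins, 15 min insulin vs saline (adjusted p = 0.444) and the list oxidative phosphorylation, nuclear encoded, 15 min insulin vs saline (adjusted p = 0.821) turned direction. These were their highest values, against lowest values of 1.97e-07 and 3.35e-10 without 15 min replicate 1.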

Other observations

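The test below was chosen after the results were seen. Insulin signalling is known to exclude FOXO factors from the nucleus, so a fall of FOXO targets is one hypothesis for the response. The 18 targets found in no other list, among them Klf15, Bcl6, Cited2 and Txnip, had a median 0.160 above that of all genes at 1 h in log2. Of these, 15 of 18 lay above it, with an unadjusted camera p of 0.041 with an estimated correlation and 0.024 after cyclic loess. These are members of the list already seen to lie higher at 1 h, so this is no separate evidence. Klf15 is also known to respond to glucocorticoids, and the stress responsive list lay higher at 1 h too, which could hide a fall, so lower FOXO activity stays open.

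Among the smaller falls, the neuronal genes Rbfox1 and Dpp6 were singled out after their values were seen. All insulin against saline gave a log2 change of -0.79 (SE 0.12) for Rbfox1 and -0.61 (SE 0.08) for Dpp6, with limma adjusted p of 0.035 and 0.018. Leaving out 1 library lost these calls in 8 and 5 of 11 runs. Both were also lost in the fit without trend (adjusted p = 0.0813 and 0.0665) and without rows moving with 18S (adjusted p = 0.0814 each), and that of Rbfox1 without the filter (0.0631) and with missing values at the lowest value (0.0569). Leaving out rows moving with 18S does not alter the log2 changes of Rbfox1 and Dpp6, only their tests. The choroid plexus marker Folr1 varied widely within groups, with an SD of 1.42 at 15 min, 1.72 at 1 h and 1.81 at 6 h, against 0.15 with saline.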
